A study of Homo sapiens with 10 samples.

How the data were processed

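Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on human CD133-positive cord blood cells that had been expanded in culture for 10 to 11 days, reselected for CD133 and crosslinked with formaldehyde for 20 min. The submitters' protocols give a purity of 75 to 90% for cells carrying both CD34 and CD133, chromatin sheared to a mean of 1000 bp, 18 cycles of PCR with ligated linkers, and gel isolation of 150 to 300 bp products, which carry 50 to 200 nt of genomic insert. There were 10 libraries: 2 runs each for TAL1, PU.1 and IKAROS, 3 runs for MEIS1 and 1 input library of the same kind of chromatin without antibody. Runs were grouped by the antibody in the labels. Both TAL1 runs carry 1 biological replicate number, as do both PU.1 runs and both IKAROS runs, so each of these factors was measured in 1 biological replicate. The number is 2 for TAL1 and 1 for PU.1, IKAROS and the input, so by these numbers TAL1 is compared with the input and with those factors across biological replicates. Whether an equal number means the same cells for different antibodies was not established here. MEIS1 runs 1 and 3 have number 1 and run 2 has number 2, so MEIS1 alone has 2 biological replicates.

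Each deposited file lists the aligned reads of 1 run, with 1 signed chromosomal position per alignment. Reads were aligned with Bowtie to hg18, per the file headers and the submitters' processing notes. The Bowtie version is not given in the sources used here. The headers give a seed of 36 bases, which was taken as the read length. They separate the alignments into 2 categories, read here as reads with a single alignment and reads with 2 alignments. The second reading is an inference from the even number of lines that each file holds in that category. Positions were taken as the leftmost base on either strand, because coinciding reads of opposite strands form a peak at a distance of 0 in those coordinates. The deposited values used are positions of alignments without normalization, so no count model across samples was applied. Signal tracks were not used here.

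Reads with a single alignment on the 22 autosomes were analysed, and the sex chromosomes were left out. Because of the PCR cycles, 1 read was kept per position and strand over all runs of the same biological replicate. Single runs held 1990772 to 5311052 distinct autosomal reads, and the pooled factors held 3294949 (IKAROS) to 8835148 (MEIS1). Each read was moved 75 bp in its 3′ direction and counted in 200 bp windows at steps of 50 bp. A window was called when its count had a one-sided Poisson p at or below 1e-09 against the largest of the genome-wide rate and the depth-scaled input rate over 1, 5 and 10 kb. Called windows within 200 bp were merged. This p is a calling threshold that compares libraries. With 1 biological replicate for most factors, no test across biological replicates was run and no p is given as evidence for a factor. The genome-wide rate used the 2075808 autosomal 1 kb bins with at least 1 input read. Fold is the highest window count of a region over the background rate used there. Intervals are exact Poisson or exact binomial (Clopper-Pearson) 95% intervals unless a bootstrap over regions is named. The exact intervals cover counting error only, since PCR products are not independent molecules.

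The caller was tested on simulated data. Libraries drawn from the input rate averaged over 10 kb gave 0 regions in each of 4 draws per factor. The background used for calling is never below that same average, so this outcome was nearly fixed in advance. It does not measure false calls in the real libraries, whose input also varies over shorter distances. Of 200 planted places with a true enrichment of 20-fold, the caller recovered 87.5% at the TAL1 depth, 29% at the PU.1 depth, 20.5% at the IKAROS depth and 90.5% at the MEIS1 depth. At 40-fold it recovered 100%, 93.5%, 92% and 100%. Numbers of regions and the folds among called regions are therefore not comparable between factors at places of moderate enrichment. As a further background, factor and input were exchanged and regions were called in the input against each factor.

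Regions of the 4 factors were merged where they overlapped by at least 1 bp. Shared regions of a pair are merged regions that hold both factors, and shares divide their number by the regions in the shorter list. They were set beside 100 random placements of the shorter list in input-covered parts of the same chromosome. They were also set beside the number expected from independent lists over the covered bins. A run was counted as holding a region when its reads exceeded 2 times its scaled input, or 2 times the genome-wide rate where that was larger. At the depth of these runs a few reads can meet this bar. Signal at the regions of another factor was the number of reads within 250 bp of the summit over the reads 2 to 3 kb away on both sides, per base, divided by the same value of the input, with a bootstrap of 500 draws over regions. Correlations across merged regions used log2(RPM + 0.5), where RPM are distinct reads scaled to 1e+06 distinct autosomal reads of the library.

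The regions named in the text follow a rule fixed before the data were examined. For each factor they are the 5 called regions with the highest ratio of reads to scaled input, with 1 added on both sides, among regions above 2 times scaled input in every run, and the 3 regions called for that factor alone with the highest fold. Beyond those, they are the 5 regions called for all 4 factors with the highest value of their lowest fold. Coordinates are hg18 and count from 1. The annotation at hand is of another build, GRCh38.p14, so no region was joined to a gene. Comparisons of gene lists, motifs and distance to transcription starts that had been fixed beforehand were therefore not run. The calling threshold, the duplicate rule, the input scaling, the read shift, equal depths, single runs, a fold minimum and the overlap rule were varied, and 3 kinds of alternative were added after seeing the data. A test for a fixed leak of PU.1 signal into IKAROS was rewritten before it was run, because its first form compared regions picked for their IKAROS signal. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.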

Results

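Binding of 4 transcription factors was measured in expanded human cord blood stem and progenitor cells to compare where TAL1, PU.1, IKAROS and MEIS1 sit in cells prepared in the same way. TAL1 is a basic helix-loop-helix factor required for blood formation, PU.1 is an ETS-family factor of the myeloid and B lineages, IKAROS is a zinc finger factor of lymphoid development, and MEIS1 is a homeodomain partner of HOX proteins. The data comprised 2 TAL1 runs with 5311052 and 4748721 distinct autosomal reads, 2 PU.1 runs with 2610345 and 2409488, 2 IKAROS runs with 2076257 and 1990772, 3 MEIS1 runs with 3883651, 3247770 and 4263722, and 1 input library with 5378568. Signal in a region is given as RPM, its distinct reads scaled to 1e+06 distinct autosomal reads of the library. Distinct positions made up 95.6% of the input reads. They made up 60.7 to 77.8% of the reads in the TAL1, PU.1 and IKAROS runs and 30.3 to 47.3% in the MEIS1 runs.

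PU.1 had by far the most called regions. The pooled PU.1 reads gave 11675 regions, MEIS1 gave 1823, IKAROS 869 and TAL1 289. The PU.1 regions held 6.31% of the distinct PU.1 reads and 0.343% of the input reads. The MEIS1 regions held 0.572% of MEIS1 reads, the IKAROS regions 0.570% of IKAROS reads and the TAL1 regions 0.0809% of TAL1 reads. Median fold over background was 31.5 for IKAROS, 28.7 for PU.1, 14.6 for TAL1 and 14 for MEIS1, which does not rank the factors, since the libraries with more distinct reads also allow regions of lower fold to be called. Exchanging factor and input gave 12 regions for TAL1, 8 for PU.1, 5 for IKAROS and 4 for MEIS1, which is 4.15% of the TAL1 number and under 1% of the others. With every factor and the input thinned to 3294949 distinct reads the order of PU.1 and TAL1 at the ends was kept, with 10118 PU.1, 873 IKAROS, 500 MEIS1 and 45 TAL1 regions. Keeping all reads gave 6017 regions for TAL1, 42932 for PU.1, 10383 for IKAROS and 112255 for MEIS1.

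**Figure D1:**
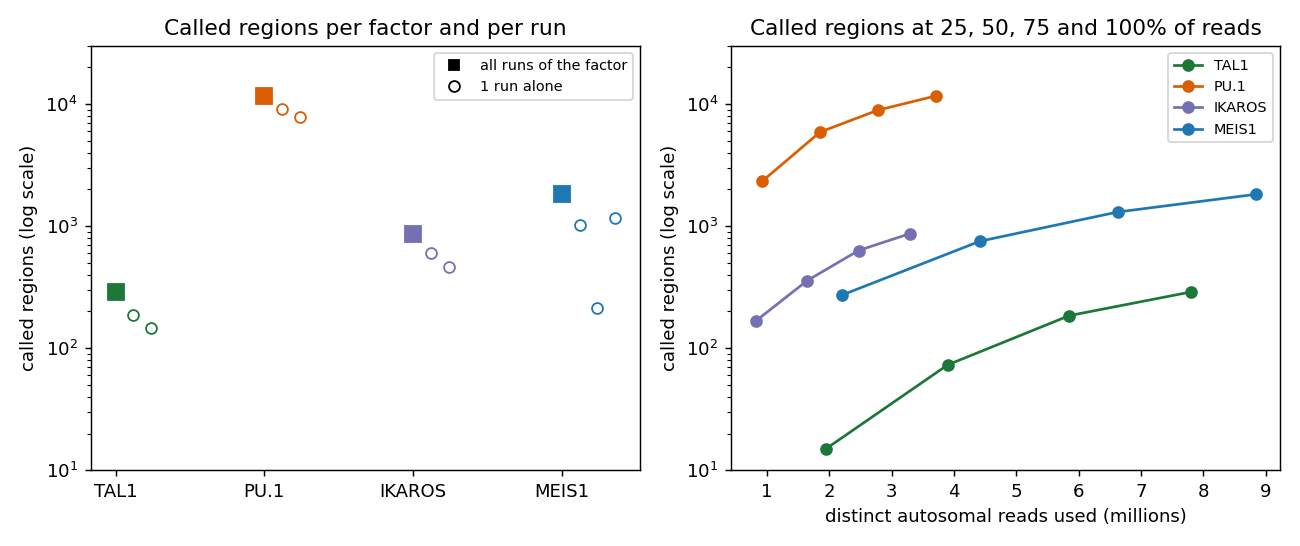
Called regions per factor on a log axis, with filled squares for all runs of a factor and open circles for single runs (left), and called regions against distinct autosomal reads used, at 25, 50, 75 and 100% of reads (right). PU.1 has 11675 regions from fewer reads than the 1823 of MEIS1 or the 289 of TAL1, and no line is flat at full depth.

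PU.1 regions had a median width of 350 bp and folds up to 210. The PU.1 region with the highest ratio to input lay on chromosome 9 at 91327001 to 91327550, with 23.2 RPM (95% interval 18.6 to 28.7), a fold of 172 and 0 input reads. Its runs held 26.4 (20.6 to 33.5) and 26.6 (20.5 to 33.9) RPM. TAL1 had 0.256 (0.0311 to 0.926), MEIS1 0.792 (0.319 to 1.63) and IKAROS 1.82 (0.668 to 3.96) there. The next by ratio lay on chromosome 2 at 60519951 to 60520450 (fold 116), chromosome 1 at 9612201 to 9612750 (160), chromosome 3 at 195042351 to 195042850 (179) and chromosome 2 at 239839801 to 239840350 (154). All 5 were called for PU.1 alone. Among regions called for PU.1 alone, the highest fold was 210 on chromosome 21 at 33361601 to 33362150, followed by 207 on chromosome 7 at 75871301 to 75871800 and 196 on chromosome 13 at 51384901 to 51385400.

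**Figure D2:**
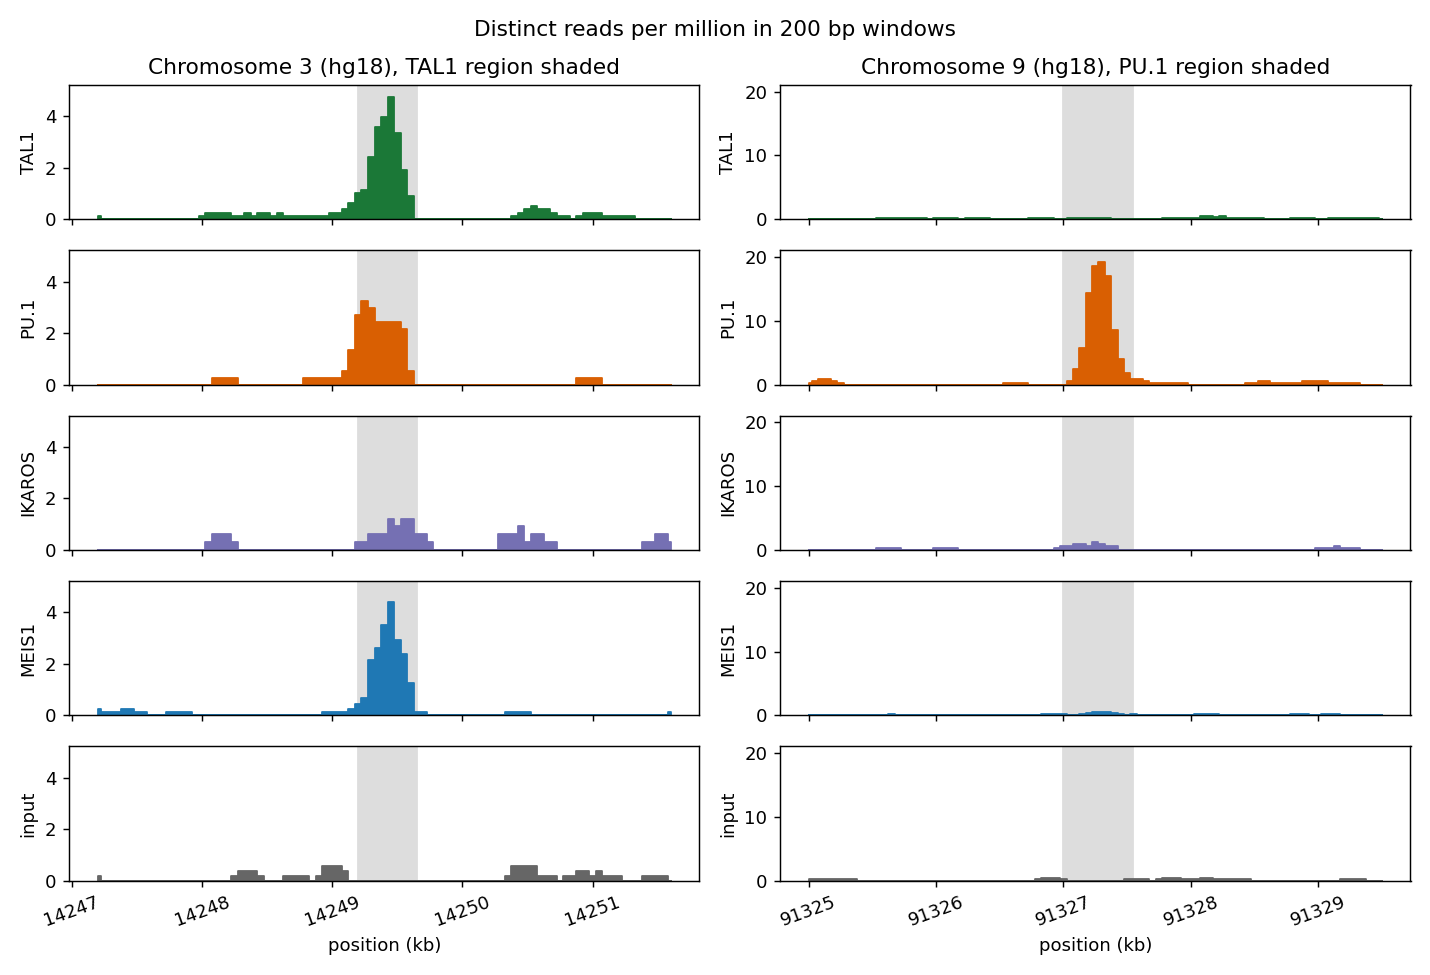
RPM in 200 bp windows (y axis, common scale within a column) against hg18 position in kb, for each factor and the input, at the TAL1 region with the highest ratio to input on chromosome 3 (left) and the PU.1 region with the highest ratio on chromosome 9 (right), shaded. TAL1, PU.1 and MEIS1 rise together on the left, where all 3 were called, and on the right PU.1, the factor called there, is far above the others.

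IKAROS regions were fewer, with a median width of 300 bp. The highest ratio to input was on chromosome 5 at 71182301 to 71182900, with 40.7 RPM (34.1 to 48.2) and a fold of 343. This place was also called for PU.1 (fold 70) and MEIS1 (67.0). The distance from the median plus-strand to the median minus-strand 5′ end of the IKAROS reads was 49.5 bp there, where its median over regions called for IKAROS alone was 151 bp (146 to 155, bootstrap). The widest IKAROS region, 2150 bp on chromosome 20 at 26136551 to 26138700, had 151 RPM (138 to 165) and a fold of 400, and was called for all 4 factors. Chromosome 1 at 154452651 to 154453450 had a fold of 258 for IKAROS and was also called for TAL1 and MEIS1. There, the distance was -31.5 bp. The remaining 2 by ratio, on chromosome 4 at 186123051 to 186124100 (fold 94.5, strand distance 569 bp) and chromosome 10 at 5971701 to 5972250 (189, 174 bp), were called for IKAROS alone. So were chromosome 19 at 60802551 to 60803100 (214) and chromosome 9 at 129869201 to 129869750 (195), which together with the chromosome 10 region had the highest fold among regions called for IKAROS alone. Run 2 alone gave 463 IKAROS regions and run 1 alone 600.

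MEIS1 regions had folds up to 75.1. The highest ratio to input was on chromosome 3 at 158808251 to 158808750, with 8.04 RPM (6.28 to 10.1) and a fold of 51.0. Its 3 runs held 10.8 (7.79 to 14.6), 5.85 (3.52 to 9.14) and 11.0 (8.10 to 14.7) RPM. The chromosome 5 place led by IKAROS came next for MEIS1, at 71182401 to 71182900, with 2.46 RPM (1.06 to 4.85) in run 2 against 7.72 (5.21 to 11.0) and 10.8 (7.90 to 14.4) in runs 1 and 3. It was not called from biological replicate 2 alone, and its strand distance was 56.5 bp for MEIS1, against a median of 128 bp (123 to 132) over regions called for MEIS1 alone. Chromosome 4 at 7702501 to 7703000 was shared with PU.1 (folds 56.4 and 92.4). Chromosome 14 at 105399351 to 105399800 had a fold of 15.2 beside an input rate of 2.32 times the genome-wide rate, so that it was lost without regions of high input, and was not called from biological replicate 2 alone either. Chromosome 2 at 44443251 to 44443650 had a fold of 45.7. Called for MEIS1 alone with the highest fold were chromosome 6 at 111110251 to 111110750 (68.1), chromosome 3 at 49250801 to 49251300 (67.0) and chromosome 2 at 8042251 to 8042750 (60.9).

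TAL1 had the fewest regions, with folds up to 42.5. The highest ratio to input was on chromosome 3 at 14249201 to 14249650, with 5.77 RPM (4.21 to 7.72), a fold of 42.5 and 0 input reads. PU.1 (fold 29.0) and MEIS1 (39.6) were called there too. Chromosome 1 at 224253701 to 224254150 (fold 26.3) and chromosome 9 at 131681201 to 131681600 (30.6) were called for TAL1 alone, with strand distances of 186.5 and 180.5 bp, and the chromosome 9 region was not called with the libraries thinned to equal distinct reads. At chromosome 20, 26137851 to 26138250, inside the wide IKAROS region, the TAL1 fold was 20.7 and the strand distance 3.5 bp. Chromosome 12 at 116050201 to 116050800 had a TAL1 fold of 35.6 and a MEIS1 fold of 67.5, but fewer than 3 TAL1 reads on 1 of its strands. After the chromosome 9 region, the highest folds for TAL1 alone were on chromosome 1 at 164941301 to 164941650 and chromosome 3 at 151930101 to 151930450, each 26.6. Run 1 alone gave 187 TAL1 regions and run 2 alone 146, and the count moved to 452 at a p of 1e-07 and 150 at 1e-12. The strand cross-correlation at its peak over lags of 50 to 300 bp, relative to lags from 300 bp on, was 1.19 for TAL1. It was 1.23 for the input, 1.33 for MEIS1, 1.68 for IKAROS and 2.24 for PU.1. At the lag of the read length the values were 1.189 for TAL1, 1.286 for the input, 1.301 for MEIS1, 1.575 for IKAROS and 1.523 for PU.1. Only for PU.1 was the peak far above that value, so for the others it is no clean measure of enrichment. Few bound places and weak enrichment of the TAL1 library were therefore not told apart.

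Repeat runs held the same places. Of the 9134 regions called in PU.1 run 1, 100% (99.96 to 100) were above 2 times scaled input in run 2, beside 15.6% of random places. For IKAROS run 1 the share was 100% (99.4 to 100), and for TAL1 run 1 it was 100% (98.1 to 100), with 17.7% and 11.2% of random places. Across the 14014 merged regions, which are not independent replicates, repeat runs correlated at a Pearson r of 0.94 for PU.1, 0.92 for MEIS1 runs 1 and 3, 0.82 for IKAROS and 0.79 for TAL1 (Spearman rho 0.89, 0.86, 0.67 and 0.62). Runs of the same biological replicate had 38.8 to 65.9% of the distinct positions of the smaller run in common. MEIS1 runs of different biological replicates had 0.345 and 0.367%, near the 0.376 to 0.589% between run 1 of different factors. The repeat runs therefore do not measure variation between biological samples.

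The 2 biological replicates of MEIS1 differed in number of regions. Replicate 1 gave 1512 regions from 5587378 distinct reads and replicate 2 gave 213 from 3247770, with 169 merged regions called in both. Of the replicate 1 regions, 84.9% (83.0 to 86.7) were above 2 times scaled input in replicate 2, against 15.9% of random places. Of the replicate 2 regions, 95.8% (92.1 to 98.1) were above it in replicate 1. A few reads can meet this bar at these depths, so the shares do not show that regions were called again. Both shares were lower at a stricter bar, which was chosen after seeing the data and is given below. Pearson r across merged regions was 0.64 between run 2 and each of runs 1 and 3.

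Most regions were called for 1 factor only. This does not show that the other factors were absent, since 20.5% and 29% of simulated 20-fold places were recovered at the IKAROS and PU.1 depths. Of the 14014 merged regions 96.1% were called for a single factor (80.0% for PU.1 alone, the longest list), 484 for 2, 49 for 3 and 19 for all 4. Regions called for 1 factor alone made up 96.0% of the PU.1 list, 78.6% of IKAROS, 77.3% of MEIS1 and 57.6% of TAL1. Shared regions were nevertheless more numerous than in random placements for every pair. The placements treat all input-covered bins alike, so any common preference for certain places, such as those of high input, would also give an excess. MEIS1 and PU.1 shared 336 regions, 18.4% of the MEIS1 list (16.7 to 20.3), beside a random mean of 6.37. IKAROS and PU.1 shared 148, 17.0% of the IKAROS list (14.6 to 19.7), beside 3.42. TAL1 and MEIS1 shared 95, 32.9% of the TAL1 list (27.5 to 38.6), beside 0.15. TAL1 shared 59 regions with PU.1 (random mean 0.97) and 37 with IKAROS (0.09), and IKAROS and MEIS1 shared 70 (0.54). Independent lists would share 10.2, 4.89, 0.254, 1.62, 0.121 and 0.763 regions in that order. All factors were called against 1 input library, and part of the excess may come from that. TAL1 carries another biological replicate number than PU.1, IKAROS and the input, so for TAL1 a difference between factors and one between biological samples are confounded. Whether an equal number means the same cells across antibodies was not established here, so the other pairs may be confounded likewise. The TAL1 and PU.1 number was 38 without TAL1 run 1, the PU.1 and IKAROS number 92 without IKAROS run 1, and the TAL1 and MEIS1 number 63 without MEIS1 run 2. Leaving out regions whose input exceeded 2 times the genome-wide rate, a choice made after seeing the data, left 218 for PU.1 and MEIS1, 50 for TAL1 and MEIS1, 38 for IKAROS and MEIS1, 32 for TAL1 and PU.1 and 19 for TAL1 and IKAROS.

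**Figure D3:**
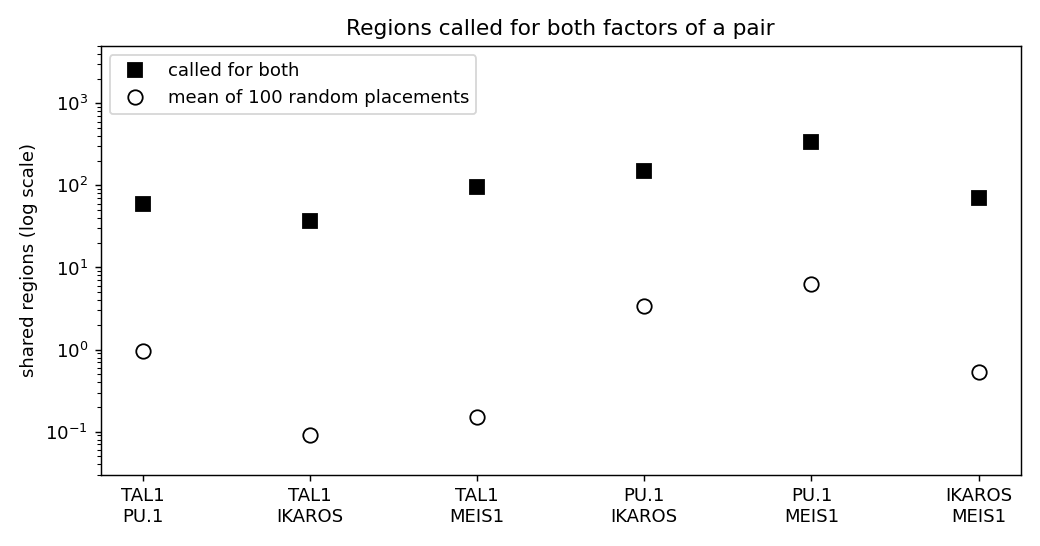
Number of regions called for both factors of each pair (filled squares) and the mean of 100 random placements of the shorter list (open circles), on a log axis. Every observed number, from 37 to 336, lies above its random mean, from 0.09 to 6.37.

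At regions not called for a factor, its signal was above the input for every pair of factor and list except TAL1 at the PU.1 and MEIS1 regions. At the 721 IKAROS regions not called for PU.1, PU.1 reads were 4.01 times more frequent at the summit than in the flanks, and 2.92 times (2.31 to 3.83) the same value of the input, or 4.41 times it when regions of high input were left out. MEIS1 signal was 2.63 times the input (2.28 to 3.09) at TAL1 regions and 2.51 times (2.29 to 2.76) at IKAROS regions not called for MEIS1. PU.1 signal was 1.60 times the input both at TAL1 regions (1.31 to 1.99) and at MEIS1 regions (1.47 to 1.73). At the PU.1 regions, MEIS1 was at 1.33 times (1.3 to 1.36) and IKAROS at 1.2 times (1.17 to 1.24) the input. There, single MEIS1 runs ran from 1.931 to 2.695 times their flanks, where the input was at 1.779 times its flanks. The interval for MEIS1 is over regions of pooled reads and does not cover this spread. IKAROS was at 1.34 times (1.15 to 1.59) the input at TAL1 regions and 1.11 times (1.05 to 1.18) at MEIS1 regions. TAL1 was at 1.29 times (1.17 to 1.45) the input at IKAROS regions and was not told apart from it at MEIS1 regions, at 1.04 times (0.990 to 1.09), although this was 1.32 when regions of high input were left out and 1.16 with all reads kept. At the 11616 PU.1 regions not called for TAL1 it lay below the input, at 0.846 times (0.825 to 0.864), and this turned to 1.02 when regions of high input were left out. The input itself was enriched at the summits, by 1.86 times over its flanks at PU.1 regions, 2.14 at IKAROS, 2.66 at MEIS1 and 3.26 at TAL1 regions. These are ratios of summed reads, so places of high input weigh heavily and a typical region can differ. At the 798 IKAROS regions not called for MEIS1 the input was at 1.007 times its flanks. At the 11338 PU.1 regions not called for MEIS1 it stayed at 1.779.

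**Figure D4:**
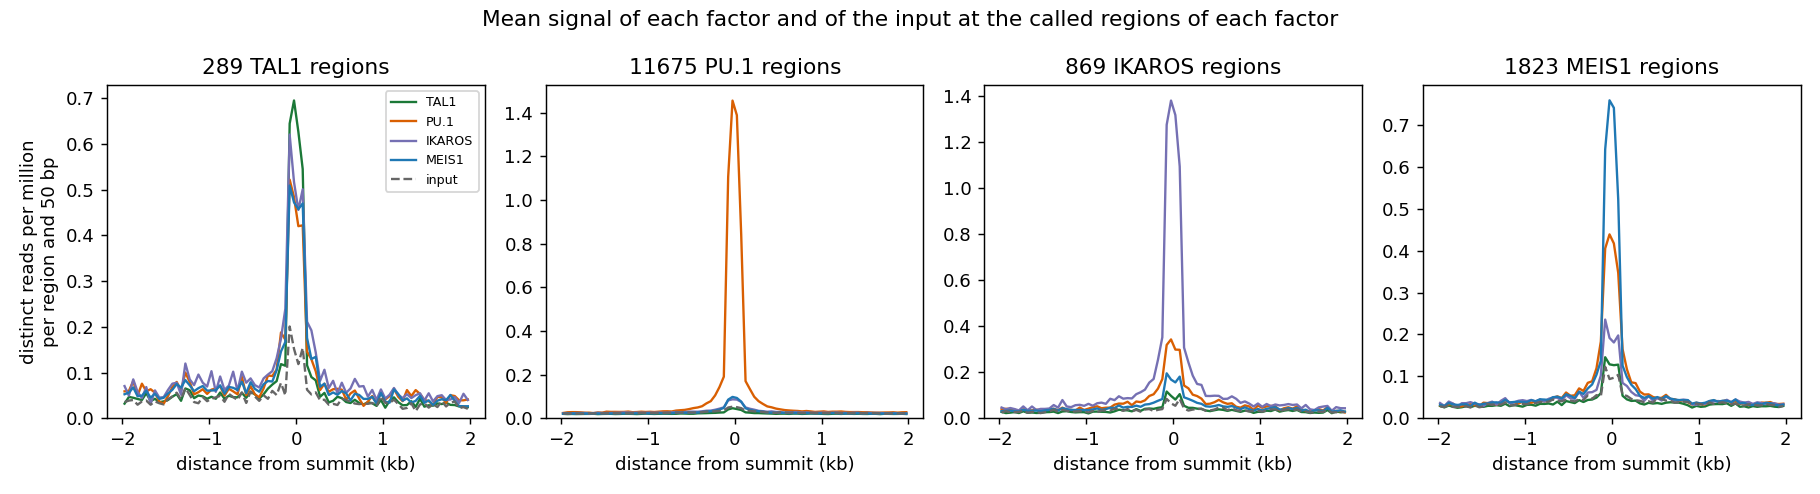
Mean RPM per region and 50 bp (y axis, own scale per panel, from 0) against distance from the summit in kb, for the 4 factors (solid) and the input (dashed), at all called regions of each factor. PU.1 is far above the other factors at its 11675 regions, whereas the other factors and the input also rise at the 289 TAL1 regions.

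The 19 regions called for all 4 factors lay mostly in places with many input reads. Their median input rate over 1 kb was 7.72 times the genome-wide rate, against 1.16 times for regions called for PU.1 or TAL1 alone, 0.772 times for IKAROS alone and 1.54 times for MEIS1 alone and for regions called for 2 or 3 factors. The region with the highest value of its lowest fold lay on chromosome 11 at 84872451 to 84873000, with folds of 34.5 for TAL1, 50.8 for PU.1, 392 for IKAROS and 53.8 for MEIS1 and an input rate of 1.16. Next came chromosome 16 at 33860451 to 33860950 (lowest fold 21.5), chromosome 14 at 87307151 to 87307650 (21.3), the wide chromosome 20 region (20.7) and chromosome 2 at 132739451 to 132740250 (17.2). The chromosome 14 region was lost for PU.1 without PU.1 run 1 and at a p of 1e-12, for TAL1 without TAL1 run 1, and for TAL1 and MEIS1 with the libraries thinned to equal distinct reads. The chromosome 20 region was lost for PU.1 without PU.1 run 1, and the chromosome 2 region for MEIS1 with biological replicate 2 alone. The median distance between plus-strand and minus-strand 5′ ends in the 19 regions was 27.5 to 34.5 bp for the 4 factors, against 116 to 151 bp in regions called for 1 factor alone. The number was 6 with a fold of at least 10 for each factor and 5 without regions whose input at the summit exceeded 2 times the genome-wide rate.

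**Figure D5:**
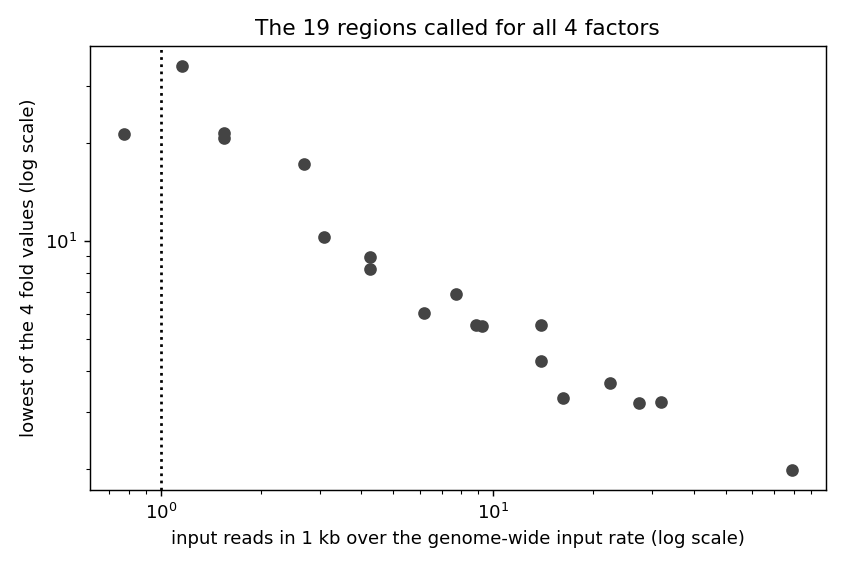
For each of the 19 regions called for all 4 factors, the lowest of the 4 folds (y axis, log) against the input reads in 1 kb over the genome-wide input rate (x axis, log; the dotted line marks 1). Lowest folds run from 34.5 down to 1.99, and input rates from 0.772 to 79.1.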

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

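The comparisons above use reads with a single alignment. Reads with 2 alignments, called in the same way against the same category of the input, also gave more regions than the exchange of factor and input. There were 520 such regions for PU.1 (23 after the exchange), 209 for MEIS1 (22), 164 for IKAROS (24) and 60 for TAL1 (24). Their median fold was 28.8 for PU.1, 30.8 for IKAROS, 11.4 for MEIS1 and 7.58 for TAL1. Both alignments of a read appear to be listed, so 1 bound place can give 2 regions.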

How the results depend on the processing

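Chosen only after seeing the data were the settings that left out regions of high input, kept all reads for the signal at the regions of another factor, or asked for 4 times scaled input in another run. Most factors have 1 biological replicate, so no test between groups and no paired analysis was run. Gene lists, motifs, distances to transcription starts and a list of regions called by the authors were planned and not run, since no annotation or genome of hg18 was at hand and no such list was used here. Of the 52 named calls 43 held under every setting run. The results keep their order at the ends (PU.1 the most regions, TAL1 the fewest) except with all reads kept, where MEIS1 had the most, and with MEIS1 biological replicate 2 alone, which gave fewer than TAL1. Depth limits the calls: 20.5% of simulated places of 20-fold enrichment were recovered at the IKAROS depth and 29% at the PU.1 depth, and from 75 to 100% of reads the number of regions still went from 8925 to 11675 for PU.1 and from 185 to 289 for TAL1. For the shifts below the cause was not tested, except that a looser p calls more regions and fewer reads call fewer.

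At a p of 1e-07 there were 452 TAL1 and 1719 IKAROS regions, and the shared numbers were 114 for TAL1 and PU.1, 63 for TAL1 and IKAROS, 161 for TAL1 and MEIS1, 276 for PU.1 and IKAROS, 572 for PU.1 and MEIS1, 111 for IKAROS and MEIS1 and 38 for all 4. At 1e-12 there were 150 TAL1, 525 IKAROS and 1156 MEIS1 regions, and 28, 24, 46, 69 and 159 shared regions for the first 5 pairs and 12 for all 4. With a fold of at least 10 the shared numbers were 37 for TAL1 and PU.1, 20 for TAL1 and IKAROS, 53 for TAL1 and MEIS1 and 6 for all 4. With all reads kept there were 6017 TAL1, 42932 PU.1, 10383 IKAROS and 112255 MEIS1 regions, and 510, 190, 888, 1077, 5246 and 937 shared regions for the pairs in the same order and 119 for all 4. Thinned to equal distinct reads there were 45 TAL1 and 500 MEIS1 regions, and 13 shared for TAL1 and PU.1, 13 for TAL1 and IKAROS, 14 for TAL1 and MEIS1, 110 for PU.1 and MEIS1, 42 for IKAROS and MEIS1 and 7 for all 4. MEIS1 biological replicate 1 alone shared 63 with TAL1. Biological replicate 2 alone gave 213 regions and shared 47 with TAL1, 51 with PU.1 and 41 with IKAROS. Without regions of high input the shared numbers were 32 for TAL1 and PU.1, 19 for TAL1 and IKAROS, 50 for TAL1 and MEIS1, 218 for PU.1 and MEIS1, 38 for IKAROS and MEIS1 and 5 for all 4. Regions within 10 kb of another of the same factor then made up 0.935% of TAL1, 14.9% of PU.1 and 4.13% of MEIS1 regions, where all called regions gave 6.57, 17.7 and 8.78%.

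Leaving out 1 run at a time gave 146 to 187 TAL1, 7884 to 9134 PU.1, 463 to 600 IKAROS and 1352 to 1512 MEIS1 regions. The shared numbers ran from 38 to 51 for TAL1 and PU.1, 29 to 35 for TAL1 and IKAROS, 63 to 88 for TAL1 and MEIS1, 92 to 117 for PU.1 and IKAROS, 244 to 289 for PU.1 and MEIS1, 56 to 68 for IKAROS and MEIS1 and 15 to 20 for all 4.

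Asking for 4 times scaled input, the share of run 1 regions held in run 2 was 96.3% for TAL1, 99.96% for PU.1 and 99.2% for IKAROS, and of run 2 regions held in run 1 it was 90.4, 99.9 and 98.1%. For MEIS1 it was 69.0% of run 1 in run 2, 98.8% of run 1 in run 3, 86.8% of run 2 in run 1 and 86.8% in run 3, 99.3% of run 3 in run 1 and 67.2% of run 3 in run 2, with 64.4% of biological replicate 1 in replicate 2 and 85.4% of replicate 2 in replicate 1.

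Leaving out regions of high input lowers the input side of the signal ratios by construction. PU.1 was then at 2.13 times the input at TAL1, 4.41 at IKAROS and 2.30 at MEIS1 regions, IKAROS at 1.78 at TAL1, 1.48 at PU.1 and 1.46 at MEIS1 regions, MEIS1 at 1.55 at PU.1 and 2.79 at IKAROS regions, and TAL1 at 1.62 at IKAROS and 1.32 at MEIS1 regions. TAL1 at PU.1 regions turned from below the input to 1.02 times it. With all reads kept TAL1 was at 0.902 times the input at PU.1, 1.46 at IKAROS and 1.16 at MEIS1 regions, IKAROS at 1.24 and MEIS1 at 1.41 at PU.1 regions.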

Other observations

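Regions lay near each other more often than in random placements, for TAL1 mostly at places of high input. Another region of the same factor lay within 10 kb of 17.7% of PU.1 regions, against a mean of 9.01% in 100 random placements, and of 8.78% of MEIS1, 7.94% of IKAROS and 6.57% of TAL1 regions, against 1.40, 0.992 and 0.235%. Without regions whose input exceeded 2 times the genome-wide rate, a setting chosen after seeing the data, the shares were 14.9% for PU.1 (random mean 7.56%), 4.13% for MEIS1 (1.07%) and 6.41% for IKAROS (0.884%), whereas the share for TAL1, 0.935% (0.224%), was within the range of the placements. The 100 kb bin from 11700001 to 11800000 on chromosome 10 held 7 PU.1 regions and 1 MEIS1 region, and bins from 28300001 and from 111800001 on chromosome 1 held 6 PU.1 regions each. The bin from 132700001 on chromosome 2 held 12 MEIS1, 11 IKAROS, 7 PU.1 and 5 TAL1 regions, and it and the next 5 bins by number of MEIS1 regions each held a region called for all 4 factors. Chromosome 19 had the highest density for every factor, with 10.7 PU.1 regions per covered Mb (9.59 to 11.8) against 5.62 over all autosomes, and 2.14 IKAROS regions (1.68 to 2.69) against 0.419.

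TAL1 regions of low fold were shared with MEIS1 more often than those of high fold, beyond counting error. In the lowest 25% of TAL1 regions by fold 56.9% (44.7 to 68.6) were also called for MEIS1, as were 30.6% (20.2 to 42.5) in the highest 25%. The shares also called for PU.1 (33.3 against 18.1%) and IKAROS (26.4 against 13.9%) went the same way, with overlapping intervals. Fold also falls with a high local input, and 13 of the 19 regions called for all 4 factors had a TAL1 fold under 10.34, the highest in that lowest 25%, so weak signal and high input were not separated here. In the PU.1 list 3.84% (3.17 to 4.60) of the lowest and 3.56% (2.92 to 4.30) of the highest 25% were also called for MEIS1. Mitochondrial reads made up 0.292 and 0.304% of the single-alignment reads in MEIS1 runs 1 and 3, 0.0912% in run 2 and 0.0125 to 0.0578% in the other libraries.

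Of the tests in the next 3 paragraphs, the distance to stretches without input reads and the comparison of shared positions among the other pairs of libraries were chosen only after the results were seen. Regions called for all 4 factors may be places of repeated sequence collapsed in the reference, since their median input rate was 7.72 times the genome-wide rate (3.09 to 13.9 in a bootstrap over regions, and above 2 times at 15 of the 19). Reads piled up without a fragment shift are also in line with the strand distance, whose lowest median was 27.5 bp (18 to 45.5, MEIS1). Of the 19 regions, 42.1% (20.3 to 66.5) lay within 1 Mb of a stretch of at least 1 Mb without input reads, against 2.11% of random places, 18.4% (8.76 to 32.0) of regions called for 3 factors, 2.89% for 2 and 0.810% for 1. Regions called for 3 factors also had short median strand distances for IKAROS (49.5 bp, 37 to 111, bootstrap) and MEIS1 (63 bp, 41 to 113). Both intervals lay below those in regions called for that factor alone. For PU.1 (61 bp, 38 to 140.5) and TAL1 (86.3 bp, 63.5 to 113.5) they overlapped. Of the regions called for 3 factors, 38.8% had an input rate above 2, although their median input rate of 1.54 was that of regions called for MEIS1 alone. By the IKAROS and MEIS1 values, piled-up reads may therefore reach beyond the 19, and by the input rates collapsed repeats may reach part of those regions. Recovery by any antibody cannot be told apart, because no library with an unrelated antibody was analysed here, and the input itself was 5.68 times (4.97 to 6.5) its flanks. The regions on chromosomes 11, 14, 16 and 20 had an input rate under 2. Their strand distances were 23 to 44.5 bp on chromosome 11 (135 for PU.1), 9 to 50 bp on chromosome 14, 17 and 27.5 bp for TAL1 and MEIS1 on chromosome 20 (107.5 for IKAROS and 511.5 for PU.1) and 54.5 to 86 bp on chromosome 16 (-326 for TAL1). Piled-up reads are therefore in line with the values on chromosome 14 and for part of the factors on chromosomes 11 and 20, and binding by all 4 factors at these places was not tested.

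IKAROS and PU.1 run 1 were sequenced on 1 flow cell and both runs 2 on another, per the file headers, so PU.1 reads in the IKAROS runs could give shared regions. Outside called regions IKAROS reads shared positions with PU.1 reads 1.35 times (1.33 to 1.38) as often as with TAL1 and MEIS1 reads, relative to the densities. This passes the 1.2 times set beforehand as the outcome if such reads are present, and PU.1 with IKAROS had the highest value of all pairs, 5.10 times the expected number, against 3.93 and 3.62 for IKAROS with TAL1 and MEIS1. PU.1 also shared more positions with TAL1 and MEIS1 (4.46 and 4.44) than these shared with each other (3.47), so the ratio is not specific to such reads, and a small number of them stays open. The excess of shared positions comes to 0.0906% of IKAROS reads. It misses any PU.1 read whose position was not also read in the PU.1 runs, so it is not the size of such a leak. The PU.1 list held 149 regions that overlap an IKAROS region, where the 148 above counts merged regions that hold both factors. If all IKAROS signal at the PU.1 regions not called for IKAROS were a fixed leak, it would be 1.94% (1.81 to 2.07) of the PU.1 signal. Such a leak would lift 6.02 PU.1 regions to the lowest read number of an IKAROS region, against those 149. This limit argues against PU.1 reads, as a fixed leak or otherwise in proportion to the PU.1 signal, as the main source of the sharing, although the ratio of shared positions alone did not, and binding of both factors at the same places stays a hypothesis.

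MEIS1 biological replicate 2 gave 213 regions and replicate 1 gave 1512. Thinned to the 3247770 distinct reads of replicate 2, replicate 1 still gave a median of 708 regions (690 to 713 in 10 draws), so fewer distinct reads alone do not account for the gap. At the regions of the other factors, which were not chosen by MEIS1, the signal over flanks was 3.34 in replicate 1 and 2.62 in replicate 2. The excess over 1 in replicate 2 was 0.692 times (0.660 to 0.727) that of replicate 1, as lower enrichment in replicate 2 would give. For the lists of other factors, single runs were compared only at regions not called from the pooled MEIS1 reads. That choice depends on MEIS1 signal, so the values below cannot be weighed against the pooled one. At the TAL1 regions not called for MEIS1, all single MEIS1 runs lay between 4.922 and 5.076 times their flanks. At the PU.1 regions not called for MEIS1 they ran from 1.931 to 2.695. Over all autosomes, the strand cross-correlation went the other way. At its peak over lags of 50 to 300 bp, relative to lags from 300 bp on, it was 1.90 in run 2 against 1.36 and 1.35 in runs 1 and 3. At the lag of the read length run 2 was also higher, at 1.625 against 1.466 and 1.429. In runs 1 and 3 these values exceeded the peak. The peak is therefore no clean measure of enrichment, and lower enrichment is not settled. A difference between the cells of the 2 biological replicates stays open and was not tested.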
